A study of Mus musculus with 6 samples.

How the data were processed

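Poly-A selected liver RNA of CD-1 mice was sequenced from 3 pools of male and 3 pools of female liver, with strand-specific libraries, per the labels. TopHat2, featureCounts and edgeR and the mouse build mm9 are named in the submitters' processing notes, with no versions and no statement of which step each served. The table used here is the authors' comparison of male with female liver. Per the file headers it holds the authors' mean FPKM per sex, a normalized ratio of male over female, the same ratio as a signed fold change, and an adjusted p-value, for the gene body and again for introns only. How the authors' p-value was adjusted, and what total and length the intronic FPKM was scaled to, are not given in the sources used here. The authors' deposited values put 929 genes at 0 FPKM in the gene body and above 0 in introns, so the gene body values exclude intronic reads. For genes of at least 1 FPKM the authors' ratio was on the median 1.04 times the ratio of the 2 mean FPKM values, so a further normalization between sexes is in it. The authors' folds are finite where a sex is at 0 FPKM, so a constant was added before the ratio was taken; no fold is printed for such genes.

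The planned tests (edgeR's quasi-likelihood test on counts, limma on per-sample FPKM, and camera and fry on gene lists) need values per pool and were not run. As fixed before the data were examined for this case, the authors' deposited comparison is described in their place, with a gene called at an authors' adjusted p under 0.05 and a further limit of a 2-fold ratio. Means are printed as the authors' means without a standard deviation. Counts of list members adjusted over the list alone were not made, because the deposited p-values are adjusted already. Nothing in the labels says whether any liver contributed to more than 1 pool.

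Library totals were recovered from the FPKM values. A small RNA gene (1228 genes of microRNA, snoRNA or snRNA type at 1 location) with a lone read in 1 pool has a mean FPKM fixed by its length and that pool's total, so totals recur over genes; 46 genes gave the 3 female totals and 40 the 3 male totals, with values within 0.00275 of a whole read. Which total belongs to which pool is unknown. No reads per gene and pool were reconstructed.

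The table lists 24197 genes with RefSeq accessions; starts were raised by 1 base so that coordinates count from 1 on mm9, as the submitters' build. RefSeq annotation of a later mouse assembly was used only for gene types, matched by accession for 23947 genes (98.97%). Symbols on more than 1 row (2 symbols, 4 rows) were not named. In all 3162 genes have more than 1 location in the table, 278 of them called, and the first is printed.

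The gene lists were fixed before the data were examined: genes reported as male-biased or female-biased in mouse liver, growth hormone and STAT5 signalling, liver transcription factors, bile acids, cholesterol, fatty acid synthesis, fatty acid oxidation, glucose, amino acids, complement, acute phase, steroid hormones, the P450, UDP-glucuronosyltransferase, sulfotransferase, glutathione S-transferase, flavin monooxygenase, major urinary protein, transporter and serpin families, ribosomal proteins, hepatocyte zones, 8 lists of other cell types or tissues, cell cycle, clock, stress responses, Y-linked genes and X-linked genes that escape silencing. A member counted as measured at a mean of at least 0.5 FPKM over both sexes (10936 genes). A list with at least 5 measured members was placed by its median log2 ratio among 10000 random lists of the same size drawn from bins of 200 genes of like mean FPKM, and percentiles under 2.5 or over 97.5 were counted as outside the central range. On simulated lists of 20 genes among 10936, 5.5% of 200 unshifted lists and 100% of 200 lists shifted by 0.5 on the log2 scale came out outside it. The simulated ratios were drawn separately for each gene, so lists whose members vary together were not covered, nor were shifts smaller than 0.5.

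Named genes followed a rule fixed beforehand: per sex, the 12 largest folds among genes called, at least 2-fold different and at 1 FPKM or more in the higher sex; the 5 most abundant of the called 2-fold genes; per list, up to 2 called members per direction with the largest fold and up to 2 uncalled members with the highest mean; and the sex-linked genes. The rule's further condition, no overlap between pools, was not applied, since it needs values per pool. This gave 187 genes, some of which are not reported here; others are marked as chosen after their values were seen or are the members that make up a small count.

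Alternatives tried were an adjusted p under 0.01, minimum means of 0.5 and 2 FPKM, folds from the mean FPKM with pseudocounts of 0.01, 0.1 and 1, quantile normalization of the means, rescaling without the 50 most abundant genes, leaving out gene families of like sequence, and the authors' intron comparison. Scripts ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.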

Results

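Liver RNA of intact adult CD-1 mice, an outbred stock, was compared between the sexes. The 6 libraries were made from poly-A selected RNA with strand-specific preparation, 3 from male and 3 from female liver. Each library was a pool: 17 livers went into each male pool and 12 into each female pool. Males were 7 to 9 weeks old and females 7 to 11 weeks, so pool size and the upper age limit went with sex. The values are the authors' mean FPKM (fragments scaled to gene length and to the library total) over the 3 pools of a sex, with their ratio and adjusted p-value for 24197 genes, once from gene bodies and once from introns only. Library totals recovered from the lowest values were 28358105, 38215906 and 41206357 reads in the female pools and 28415535, 37727874 and 42673908 reads in the male pools. The summed depths of the sexes differed by 0.962%. At this depth 1 read on a gene of 1000 bases in 1 pool adds between 0.00781 and 0.0118 to a sex's mean FPKM, so lower values rest on few reads. Values per pool were not used here, so the means carry no standard deviation. The authors' adjusted p-value depends on the spread between pools, but also on the fold and the number of reads, so it does not measure that spread.

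The sex of the libraries was checked first with Xist, the RNA that silences an X chromosome in female cells, and with genes of the Y chromosome. Xist (X, 100655712 to 100678572, build mm9) had an authors' mean of 22.5 FPKM in female and 0.0199 in male liver, so that the male value was 0.0884% of the female. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty had male means of 9.60, 16.1, 1.90 and 2.17 FPKM, and their female means were between 0.19% and 0.40% of these. A library of the wrong sex among the 3 of a group would have brought such a share to about 33.3%. Zfy1, Zfy2 and Usp9y were listed at 0 in both sexes.

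The comparison of male with female liver asks which genes differ in expression between the sexes. Beside Xist, genes with large folds toward female liver included the sulfotransferases Sult2a2 and Sult3a1, the cytochrome P450 genes Cyp3a16 and Cyp2b13, and A1bg. Beside the Y-linked genes, which had the largest male folds among the named genes, those toward male liver included Cyp4a12b, the major urinary protein Mup20 and the fatty acid elongase Elovl3. At an adjusted p under 0.05 the authors' deposited table held 1808 genes, 829 higher in male and 979 higher in female liver, among 17997 genes above 0 in either sex. The difference reached 2-fold for 232 genes in male and 300 in female liver, 10-fold for 42 and 43, and 100-fold for 6 and 16. The median fold of the genes past the threshold was 1.56 in that table. At a mean of at least 2 FPKM in either sex 259 genes were 2-fold different, and with a pseudocount of 1 FPKM 199 were, in place of 532.

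**Figure D1:**
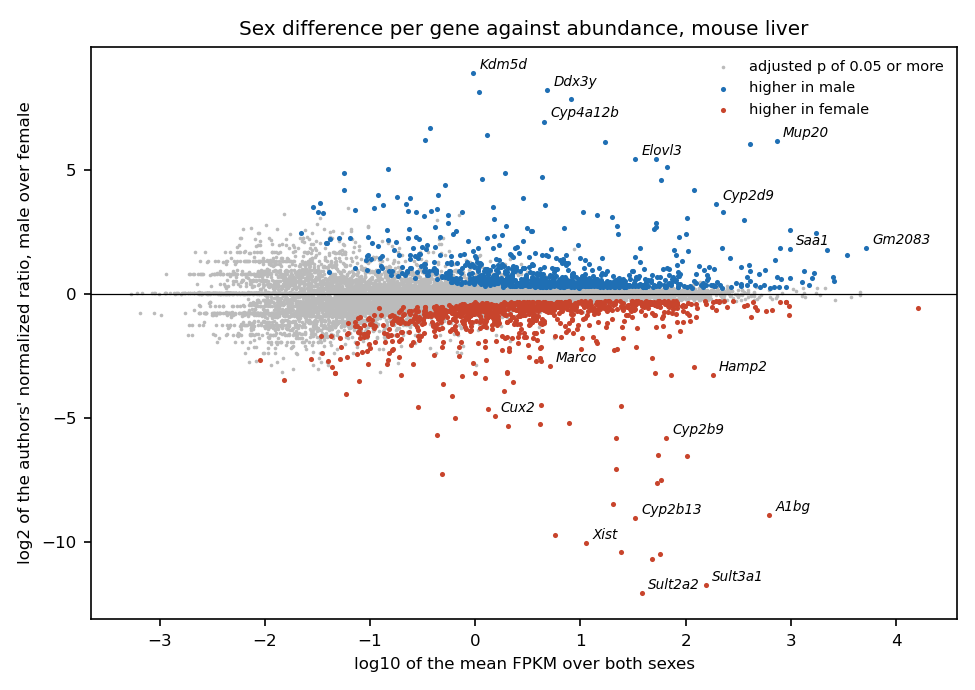
Each point is 1 of the 16557 genes above 0 FPKM in both sexes, with the log10 of its mean FPKM over both sexes on the x axis and the log2 of the authors' normalized male over female ratio on the y axis. Blue points (higher in male) and red points (higher in female) have an authors' adjusted p under 0.05, and points with large ratios include sulfotransferases, Cyp2b13, A1bg and Xist below 0 and Y-linked genes, Cyp4a12b and Mup20 above 0.

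Genes earlier reported as female-biased in mouse liver, a list chosen from prior work, were higher in female liver for 36 of 37 measured members. The other member, Lifr, did not pass the threshold. Whether that work included these samples was not checked, here or for the male-biased list. The median log2 ratio of the list was -4.50. Sult2a2, a sulfotransferase acting on hydroxysteroids and bile acids (7, 14318855 to 14364986), was listed at 76.3 FPKM in female and 0.0158 in male liver. The authors' deposited table gave Sult3a1 310.4 FPKM in female and 0.0795 in male liver, and Sult2a1 114.9 and 0.0814 FPKM with an adjusted p of 4.23e-199. Sult2a5 and Sult2a3, at 20.3 and 8.12 FPKM in female liver, were listed at 0 in male liver, and Sult2a6 was listed at 11.4 against 0.0121 FPKM. A1bg, which encodes a plasma glycoprotein (15, 60749144 to 60752825), was 482-fold higher in female liver in the authors' deposited table, at 1239 against 2.48 FPKM, with an adjusted p of 9.75e-39. Cyp2b13 (7, 26846514 to 26881215) was 532-fold higher in female liver in the authors' deposited table, with an adjusted p listed at 0. Cyp3a16 and Cyp3a41b had female means of 48.2 and 40.7 FPKM against 0.0345 and 0.105 FPKM in male liver. The predicted gene Gm4794, near Sult3a1 on chromosome 10, was listed at 96.5 and 0.0499 FPKM. Cux2, a homeobox transcription factor, was 30.4-fold higher in female liver in the authors' deposited table (2.96 against 0.0911 FPKM, adjusted p 6.76e-102). The solute carriers Slc22a26 and Slc22a27 were 56.4-fold and 37.9-fold higher in female liver in the authors' deposited table, and Acot3, an acyl-CoA thioesterase, 22.6-fold. Members of the Sult2a, Cyp3a and Cyp2b families are close in sequence, so the split of reads among them is uncertain.

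Genes earlier reported as male-biased, likewise chosen from prior work, were higher in male liver for 26 of 27 measured members, with a median log2 ratio of 3.08. The exception was Serpina1e, at 13.5 FPKM in female and 11.2 FPKM in male liver with an authors' adjusted p of 1. Elovl3, which elongates saturated and monounsaturated fatty acids (19, 46206389 to 46210184), was 44.1-fold higher in male liver in the authors' deposited table, at 64.6 against 1.53 FPKM, with an adjusted p of 1.51e-244. Cyp4a12a and Cyp4a12b, hydroxylases of fatty acids, were 43.3-fold and 124.9-fold higher in male liver in the authors' deposited table, with 103 and 9.01 FPKM in male liver. The authors' deposited table gave folds of 6.54 for Hsd3b5, a steroid dehydrogenase, 7.30 for Cyp7b1, an oxysterol hydroxylase, 7.99 for the glutathione transferase Gstp1 and 14.6 for Ugt2b38. Obp2a, an odorant binding protein of the lipocalin family, was 85.7-fold higher in male liver in the authors' deposited table at a male mean of 2.58 FPKM.

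Major urinary proteins, lipocalins that carry pheromones into urine, were higher in male liver for 15 of 17 measured members, with a median log2 ratio of 2.75, and none was higher in female liver. Mup20, the pheromone also called darcin (4, 61711269 to 61715151), was 71.7-fold higher in male liver in the authors' deposited table, at 1445 against 20.9 FPKM, with an adjusted p of 2.82e-54. Mup7 was listed at 803 against 12.4 FPKM, Mup3 at 3357 against 1007 FPKM and Mup17 at 1690 against 289 FPKM. Mup2, at 2.47 FPKM in male and 8.64 FPKM in female liver, and Mup8, at 13.5 and 3.89 FPKM, did not pass the threshold. The 21 genes of the family, with Gm2083, made up 9.79% of the summed FPKM in male and 2.55% in female liver. These genes share most of their sequence, and Gm2083 (4, 60591133 to 60675237, 8009 against 2274 FPKM) spans Mup10 and reaches into Mup11, so values of single members are uncertain. Whether reads under both Gm2083 and Mup10 enter the summed shares more than once is not known.

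Families of enzymes that clear drugs, steroids and lipids went both ways. Of 57 measured genes of P450 families 1 to 4, 13 were higher in male and 23 in female liver, and 21 did not pass. The median log2 ratio of these P450 genes was -0.03, at percentile 2.15 of random lists, and it was 0.01 at a mean of at least 2 FPKM, so the list has no stable direction. Cyp2c39 was 7.73-fold higher in female liver in the authors' deposited table and Cyp4a10, a target of the fatty acid receptor PPARA, 4.44-fold. Cyp2e1 and Cyp1a2, which oxidise small solvents and aromatic amines, did not pass (1332 against 1348 and 122 against 124 FPKM, male first). Of 12 measured sulfotransferases 9 were higher in female liver and none in male liver, and Sult2a7, Sult5a1 and Sult1b1 did not pass. The median log2 ratio of -5.60 falls in a gap between Sult1a1 (-1.48) and Sult2a6 (-9.72), with no member near it, and it was -1.87 with no low-value filter, -9.72 at a mean of at least 2 FPKM and -2.83 in introns. Glutathione S-transferases were higher in male liver for 6 and in female liver for 7 of 20 members (median log2 ratio -0.12, and 0.014 in introns). Gstp2 was 12.2-fold higher in male and Gstt3 4.75-fold higher in female liver in the authors' deposited table. Of 15 UDP-glucuronosyltransferases, which attach glucuronic acid, 7 were higher in male and 3 in female liver, with a median log2 ratio of 0.21 in gene bodies and -0.18 in introns. Ugt2b1, at 223 against 107 FPKM, was 2.16-fold higher in male liver in the authors' deposited table, while Ugt2b37 and Ugt1a5 were 4.38-fold and 4.22-fold higher in female liver. The Ugt1a genes share their last exons, so reads there cannot be assigned to a single member. Flavin monooxygenases, carboxylesterases and aldehyde oxidases were higher in male liver for 10 and in female liver for 7 of 20 members (median log2 ratio 0.32). In this group the authors' deposited table gave a 5.32-fold higher male value for the aldehyde oxidase Aox3 and a 3.92-fold higher female value for Fmo2. Of 17 organic anion and cation transporters 4 were higher in each sex, among them Slco1a1 in male (2.23-fold) and Slco1a4 in female liver (3.44-fold) in the authors' deposited table.

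In bile acid synthesis and transport 9 of 29 measured genes were higher in male and 5 in female liver. Scp2, the sterol carrier protein that also cleaves bile acid precursors, was 2.59-fold higher in male liver in the authors' deposited table at 1009 against 404 FPKM, with an adjusted p of 2.40e-58. Cyp39a1, a hydroxysterol hydroxylase, was 3.60-fold higher in female liver in the authors' deposited table. Slco1b2 and Slc27a5, the most abundant members that did not pass, had male means of 177.7 and 143.6 FPKM against 170.4 and 169.8 FPKM in female liver. Of 19 genes of steroid hormone metabolism 7 were higher in male and 5 in female liver, with a median log2 ratio of 0.14 at percentile 98.0, a place inside the central range at a mean of at least 2 FPKM. The steroid 21-hydroxylase Cyp21a1 was 4.38-fold higher in male and the steroid 17-hydroxylase Cyp17a1 15.1-fold higher in female liver in the authors' deposited table.

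Genes of amino acid breakdown and lipid synthesis lay toward female liver by small folds. Of 32 genes of the urea cycle and amino acid breakdown 17 were higher in female and 1 in male liver, with a median log2 ratio of -0.30. Got1, the cytosolic aspartate aminotransferase, and Cth, which makes cysteine, were 2.52-fold and 1.91-fold higher in female liver in the authors' deposited table, and Tdo2, the first enzyme of tryptophan breakdown, was 1.61-fold higher in male liver. Of 24 genes of cholesterol synthesis 6 were higher in female and none in male liver (median log2 ratio -0.19), among them Sqle, squalene epoxidase, at 1.42-fold in the authors' deposited table. Of 26 genes of fatty acid and triglyceride synthesis 6 were higher in female and 1 in male liver (median log2 ratio -0.13, and -0.11 and inside the central range in introns). Pnpla3, a lipid droplet protein, was 4.56-fold higher in female liver in the authors' deposited table and Acsl1, an acyl-CoA synthetase, 1.43-fold higher in male liver. Among 39 genes of fatty acid oxidation and PPARA targets 12 were higher in female and 5 in male liver, and the median log2 ratio of 0.01 lay at percentile 40.5. Fgf21, a hormone of fasting, was 3.09-fold higher in male liver in the authors' deposited table, at 1.18 against 0.393 FPKM. In glucose and glycogen metabolism 3 of 25 genes were higher in each sex, with Gys2, the liver glycogen synthase, 1.70-fold higher in male and Gckr, the glucokinase regulator, 1.30-fold higher in female liver in the authors' deposited table. Pck1 and Gapdh did not pass.

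**Figure D2:**
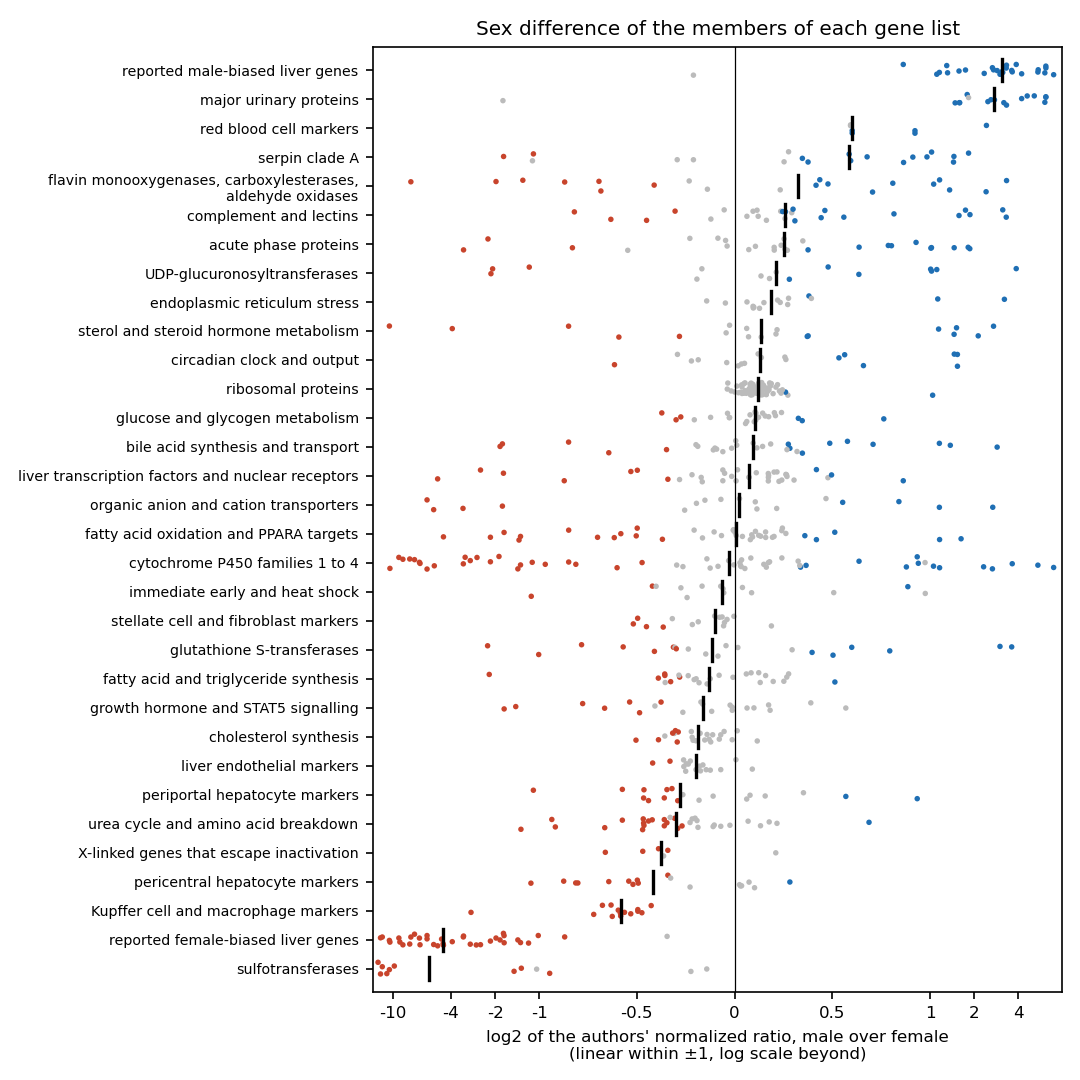
Each point is a measured member of 1 of 32 gene lists, placed by the log2 of the authors' normalized male over female ratio (linear within 1 of 0, log scale beyond), and each black bar is the list's median. Blue and red points passed an authors' adjusted p under 0.05 as higher in male or in female liver and grey points did not. The medians of the genes reported as female-biased and male-biased lie at -4.50 and 3.08, and that of sulfotransferases falls in a gap between its members.

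Several groups of plasma proteins had more members higher in male than in female liver. Of 27 complement and lectin genes 13 were higher in male and 4 in female liver, with a median log2 ratio of 0.26 in gene bodies, and 0.08 and inside the central range in introns. The complement components C4a and C6 were 9.90-fold and 8.76-fold higher in male liver in the authors' deposited table, and Mbl2, a mannose-binding lectin, 1.55-fold higher in female liver. Of 27 acute phase proteins 10 were higher in male and 3 in female liver, with a median log2 ratio of 0.25 in gene bodies, 0.08 after quantile normalization and -0.15 in introns. The serum amyloids Saa1 and Saa2, released by the liver in inflammation, were 3.53-fold and 3.64-fold higher in male liver in the authors' deposited table (1509 against 445 and 1218 against 348 FPKM), with adjusted p-values of 2.86e-06 and 1.29e-05. Hamp2, a hepcidin gene, was 9.70-fold higher in female liver in the authors' deposited table, at 330 against 32.7 FPKM, and Orm3 4.71-fold. The fibrinogen genes Fgb and Fgg did not pass. Of 19 serpin clade A genes, which encode protease inhibitors and hormone carriers, 12 were higher in male and 2 in female liver (median log2 ratio 0.59, and 0.34 after quantile normalization). Serpina12, an insulin-sensitising adipokine, and Serpina1d were 3.56-fold and 2.74-fold higher in male liver in the authors' deposited table, while Serpina6, the corticosteroid carrier of plasma, was 2.14-fold higher in female liver. The close copies within Serpina1, Serpina3, Saa and Orm make single members uncertain.

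Among 36 liver transcription factors and nuclear receptors 7 were higher in female and 3 in male liver, and 26 did not pass. Besides Cux2, the HMG-box factor Tox was 5.70-fold higher in female liver in the authors' deposited table, and Bcl6, a repressor that binds STAT5 sites, was 1.82-fold higher in male liver with an adjusted p of 0.00176. In introns the Bcl6 log2 ratio was -0.04. Hnf4a and Cebpa, central hepatocyte regulators, had male means of 65.9 and 67.0 FPKM against 70.8 and 61.6 FPKM in female liver and did not pass. Of 21 genes of growth hormone and STAT5 signalling 7 were higher in female and none in male liver (median log2 ratio -0.16). The prolactin receptor Prlr and Igfbp1, a binding protein of insulin-like growth factors, were 3.33-fold and 2.72-fold higher in female liver in the authors' deposited table. The growth hormone receptor Ghr did not pass (73.3 against 67.0 FPKM, male first). Of 18 genes of the circadian clock and its output 6 were higher in male and 1 in female liver, and the median log2 ratio was 0.13 at percentile 97.8, or 0.11 and inside the central range after quantile normalization, and 0.35 at percentile 99.98 in introns. Ciart and Tsku, which cycle over the day, were both 2.90-fold higher in male liver in the authors' deposited table, and Npas2, a partner of the clock factor BMAL1, was 1.53-fold higher in female liver. Of 16 genes of endoplasmic reticulum stress 3 were higher in male liver, with a median log2 ratio of 0.19 that was inside the central range at a mean of at least 2 FPKM (0.13) and in introns (0.12). They were led by Asns, asparagine synthetase, at 9.28-fold in the authors' deposited table and 0.994 FPKM. Among 14 immediate early and heat shock genes 1 was higher in male and 2 in female liver. Of 77 ribosomal protein genes 2 were higher in male liver, Rps4l and Rpl35a, and 75 did not pass (median log2 ratio 0.12, 0.06 after quantile normalization, and 0.02 and inside the central range in introns).

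Markers of hepatocyte zones lay toward female liver at both ends of the lobule. Of 18 pericentral markers 10 were higher in female and 1 in male liver (median log2 ratio -0.42), and of 18 periportal markers 9 and 2 (median log2 ratio -0.28). The periportal list shares Sds, Hal, Gls2, Ass1, Asl, Cps1, Uroc1 and Arg1 with the list of the urea cycle and amino acid breakdown. The pericentral list shares Glul with that list, so the periportal and amino acid medians are not separate results. Oat, ornithine aminotransferase of pericentral cells, was 2.20-fold higher in female liver in the authors' deposited table, and so was the periportal marker Ctsc, cathepsin C, at 2.14-fold. The periportal P450 gene Cyp2f2 was 1.91-fold higher in male liver in the authors' deposited table.

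Markers of other liver cell types were measured beside these groups. Kupffer cell and macrophage markers were higher in female liver for 15 of 15 measured members, with a median log2 ratio of -0.58. Marco, a scavenger receptor of macrophages (1, 122371115 to 122401661), was 7.55-fold higher in female liver in the authors' deposited table, at 9.08 against 1.15 FPKM, with an adjusted p of 3.18e-06, and Folr2 was 1.65-fold higher. Endothelial markers were higher in female liver for 2 of 17 members (Oit3 and Gpr182), with a median log2 ratio of -0.20, and -0.05 and inside the central range in introns. Stellate cell and fibroblast markers were higher in female liver for 4 of 15 members, with a median log2 ratio of -0.10 at percentile 3.24. The stellate median was outside the central range after quantile normalization (-0.12), at a mean of at least 2 FPKM (-0.14) and in introns (-0.30). The 3 lymphocyte markers measured, Ccl5, Cd52 and Ptprc, were higher in female liver, and the neutrophil markers S100a8 and S100a9 did not pass. Red blood cell genes were higher in male liver for 5 of 7 members (median log2 ratio 0.60), with Alas2, the erythroid enzyme of heme synthesis, 5.36-fold higher in the authors' deposited table. In introns 5 members had signal and only 1, Alas2, was called, and the median log2 ratio of 1.57 was the value of Alas2 itself. Pairs of globin genes share their reads, so these 7 members carry fewer separate values. Of 4 bile duct markers Spp1 was higher in male liver, of 3 adipose and pancreas markers Cidec was, and of 4 cell cycle genes Tk1 was higher in female liver.

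The X chromosome held 1059 of the listed genes, of which 45 were higher in female and 16 in male liver, at any mean FPKM. Of its 302 measured genes (a mean of at least 0.5 FPKM over both sexes) 14.6% passed the threshold. On the autosomes 934 of 23021 genes were higher in female and 809 in male liver, and 13.8% of the 10629 measured genes passed. Of 6 measured X-linked genes known to escape silencing 4 were higher in female liver, with Eif2s3x 1.58-fold and Kdm6a 1.39-fold higher in the authors' deposited table. Of 3574 genes with only non-coding transcripts 41 passed the threshold as higher in male and 33 as higher in female liver. Of the 574 measured among them 8.71% passed.

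Of the 33 lists with at least 5 measured members, 26 had a median outside the central range of random lists of like expression, 13 toward each sex. By chance 1.65 would be outside if the members of a list varied independently, which was not tested. The lists of reported male-biased and female-biased genes and of Y-linked genes and Xist were chosen for a known sex difference. Other lists share members with them and with each other. These percentiles describe the mean values of the sexes and are not tests over pools. Red blood cell and macrophage markers moved with sex beside every group above, at median log2 ratios of 0.60 and -0.58.

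The second comparison asks whether differences seen in gene bodies are also seen in introns, whose reads come mostly from unspliced RNA. Elovl3, Cyp7b1, C6 and Mup20 were higher in male introns too, by 94.5-fold, 6.92-fold, 10.9-fold and 75.9-fold in the authors' deposited table. Sult3a1, Cyp2b13, A1bg and Cux2 were higher in female introns, by 1104-fold, 432-fold, 307-fold and 18.6-fold in the authors' deposited table. Scp2 was 4.31-fold higher in male introns in the authors' deposited table, and Prlr 2.90-fold higher in female introns. By contrast, Saa1 and Saa2 had intron folds of 1.38 and 1.29 with adjusted p-values of 1 in the authors' deposited table, at intronic means of 18.7 and 12.8 FPKM in male liver.

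At an adjusted p under 0.05 the introns gave 523 genes, 291 higher in male and 232 in female liver, and 311 of them differed at least 2-fold (169 and 142). Of the 15640 genes above 0 in both parts, 786 were called higher in male gene bodies and 287 in male introns, with 220 in both, where independent lists would share 14.4. Toward female liver the numbers were 938 and 229, with 186 in both and 13.7 for independent lists. Of 494 genes with a 2-fold gene body difference and intronic signal, 457 (92.5%) had an intron ratio in the same direction and 248 an intron call in it. Over the 453 of them above 0 in the introns of both sexes, Pearson's r of the log2 ratios was 0.923 and Spearman's rho 0.892, across genes, which are not independent replicates. Choosing genes by a large gene body difference leaves out ratios near 0 and can raise both values, so they do not describe all genes.

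Opposite calls were found in 3 genes, named here after their values were seen. Rcan2, a calcineurin regulator, was 2.52-fold higher in female gene bodies and 4.51-fold higher in male introns in the authors' deposited table. Ugt1a6b and Ugt1a9 were 1.55-fold and 1.21-fold higher in male gene bodies and 1.67-fold and 1.51-fold higher in female introns in the authors' deposited table. The introns of the Ugt1a genes hold first exons of other members of the cluster. Gene bodies and introns come from the same libraries and share their chance differences, and the difference between the parts was not tested. Among genes at least 2-fold different, the median intronic mean was 0.00891 FPKM in those without an intron call and 0.113 FPKM in those with one, though some without a call were well above this, such as Saa1 at 16.9 FPKM.

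**Figure D3:**
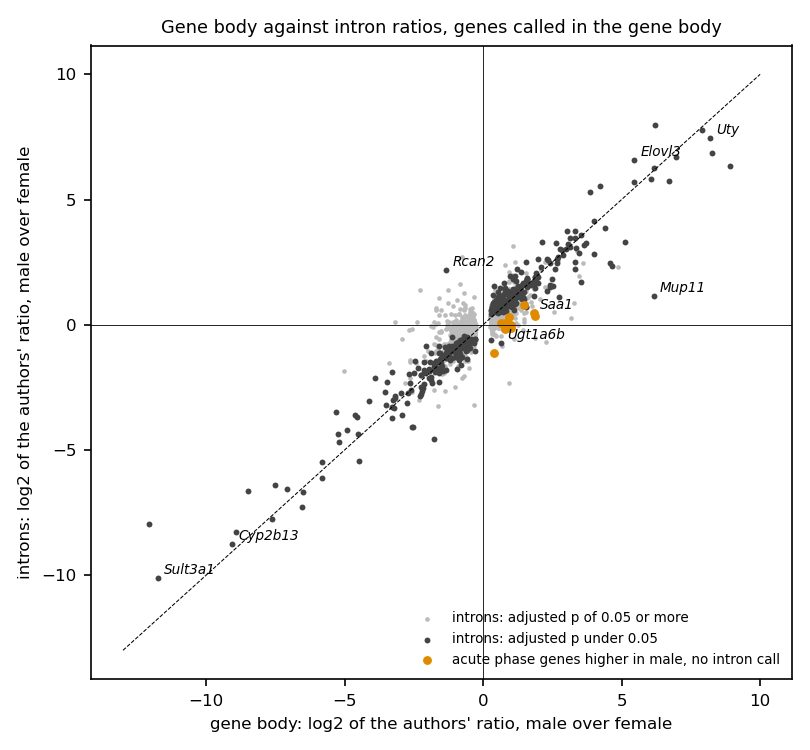
Each point is 1 of 1673 genes with an authors' adjusted p under 0.05 in the gene body and signal above 0 in both parts and sexes, with the log2 of the authors' male over female ratio in the gene body on the x axis and in introns on the y axis. Dark points also passed in introns, orange points are the 10 acute phase genes higher in male gene bodies without an intron call, and the dashed line marks equal ratios.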

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

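The alternatives using introns, a minimum of 0.5 FPKM, a pseudocount of 0.1 or no listed gene families, and for the gene lists those using the 50 most abundant genes or 2 FPKM, were chosen after seeing the data. No paired analysis was possible because the table holds a mean per sex, with no value that carries a pool number; for the same reason the replicate block, leaving out each pool, other splits of the pools, DESeq2 and its size factors, voom, camera and fry were not run, so how far 1 pool decides a call is open. Of 1808 genes different between the sexes, 1180 had a mean of at least 2 FPKM in either sex. The intron comparison called 523 genes, not all of them among the 1808. Those higher in male liver went from 829 to 291 in introns, and those higher in female liver from 979 to 636 at an adjusted p under 0.01, 571 at 2 FPKM and 232 in introns. Genes at least 2-fold different went from 532 to 259 at 2 FPKM, 311 in introns and 199 with a pseudocount of 1. In male liver these were 124 at 2 FPKM and 92 with a pseudocount of 1, in place of 232. In female liver they were 135 at 2 FPKM, 194 at 0.5 FPKM, 142 in introns and 107 with a pseudocount of 1, in place of 300. The filters and the stricter threshold lower a count by construction, and a pseudocount shrinks folds of low genes; the cause of the lower intron counts was not tested, apart from the lower intronic FPKM of genes without an intron call. Quantile normalization gave 528 genes at least 2-fold different and rescaling without the 50 most abundant genes 524; both moved the median of all genes by less than 0.1 on the log2 scale, with the authors' calls kept, and quantile normalization turned 7 called genes, none of them at least 2-fold different. The number of lists outside the central range was 26 of 33 with a percentile, 19 of 32 in introns, 22 of 32 at 2 FPKM and 28 of 38 without a low-value filter; the list of Y-linked genes and Xist had too few members in introns and at 2 FPKM, and without the filter 5 further lists had enough, while 1 of the 33 went inside and none outside. Lists that went inside the range were the clock list after quantile normalization and at 2 FPKM, steroid hormones at 2 FPKM, endoplasmic reticulum stress at 2 FPKM and in introns, the P450 families without a low-value filter, without the 50 most abundant genes, at 2 FPKM and in introns, and fatty acid synthesis, complement, ribosomal proteins, glutathione S-transferases and endothelial markers in introns. Stellate markers went outside it after quantile normalization, at 2 FPKM and in introns. The median log2 ratio changed sign to 0.012 for the P450 families at 2 FPKM, and in introns to -0.15 for acute phase proteins, -0.18 for UDP-glucuronosyltransferases and 0.014 for glutathione S-transferases. Acute phase proteins and UDP-glucuronosyltransferases lay outside the range toward male liver in gene bodies, at percentiles 99.9 and 99.7. In introns both lay outside it toward female liver, at 1.3 and 2.3. The 19 lists outside in introns thus include these lists, on the other side, and the stellate list, which was inside in gene bodies. Of the named genes, 5 called ones changed sign in introns: Bcl6 (-0.044), Cd52 (0.10), Chac1 (-0.57), Ldha (-0.15) and Oit3 (0.65), none with an intron call, and 34 lost the call while keeping the direction. The cause of these sign changes was not tested. The highest share of the lower sex's mean in the higher sex's mean among sex-linked genes, 0.40%, became 42.4% in introns. That value came from Usp9y at 5.71e-05 and 1.35e-04 FPKM, which few reads give. The share does not ask which sex is higher, and Y-linked Zfy2 had 1.32e-04 FPKM in female introns and 0 in male introns. Over the genes above 0 in the gene body, a restriction added after the 42.4% was seen, the share was 1.23%.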

Other observations

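All tests in this part were chosen after the results were seen. Some families of immune genes were picked after their values were seen, with no test of enrichment. Of 11 measured guanylate-binding protein genes, which act against intracellular pathogens, 8 were called and all 8 were at least 2-fold higher in female liver, with a median fold of 2.71 over the 11. Gbp3 and Gbp7 were 3.70-fold and 3.02-fold higher in female liver in the authors' deposited table (adjusted p 1.15e-07 and 7.84e-09). Of 8 MHC class II genes and Cd74, 6 were called higher in female liver, of 6 immunity-related GTPases 4, and of the chemokines Cxcl9, Cxcl10, Cxcl13, Ccl2 and Ccl5 all 5, with none of these families' measured members called higher in male liver. Intron calls toward female liver numbered 4 for the guanylate-binding proteins, 2 for the GTPases, 1 for the chemokines and 0 for the MHC class II genes and Cd74. Immune cells express many of these genes, and the macrophage markers (15 of 15, median log2 ratio -0.58) and the lymphocyte markers (3 of 3, Ccl5 among them) were higher in female liver too. Cxcl13, which attracts B cells, was 8.78-fold and Tgtp1 5.94-fold higher in female liver in the authors' deposited table; Tgtp1 and Tgtp2 are near copies and share reads. The adjusted p-values of the 23 called genes lay at the median percentile 86 among called genes of like fold and expression, so most of them had a weaker p than genes of like size.

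Genes with large sex differences lay close together. Of 295 measured genes at 1 location that were at least 2-fold different, 112 (38.0%) had another such gene higher in the same sex within 200 kb, against a median of 20 and at most 45 in 1000 random draws of like genes. Without major urinary proteins 98 had such a neighbour. The groups were mostly gene families, such as Cyp2c40, Cyp2c69, Cyp2c37 and Cyp2c54 (19, 39841563 to 40148303) and Cyp2b10, Cyp2b13, Cyp2b9 and Cyp2a4 (7, 26682677 to 27100107). A group outside the liver enzyme families, higher in male liver, held microRNA genes of the Mir290 cluster (Mir292, Mir292b, Mir293 and Mir294) with D7Ertd143e and Nlrp12 (7, 3218785 to 3249741). Reads shared by near copies add to such counts and were not removed. Whether members of a group overlap was not checked when the groups were formed, so reads of 1 transcript may lie behind several of the microRNA genes. Alb, the gene of serum albumin, had the highest FPKM of a called gene, 19411 in female and 12608 in male liver. Among 35 genes at least 8-fold different with a mean of at least 10 FPKM, 4 (Mup11, Cyp2c40, Cyp2c69 and Mup12) had an adjusted p at percentile 90 or higher for their fold and expression. Percentiles place about this share of genes so high by the way they are made, so the count sets none of them apart. The genes compared were not matched for gene length or number of reads.

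Kupffer cell and macrophage markers were higher in female liver for 15 of 15 members. A lower share of hepatocytes in the female pools would raise markers of other cell types alike, but the endothelial median lay 0.385 above the macrophage median on the log2 scale and the interquartile ranges of their members (-0.25 to -0.15 and -0.63 to -0.51) did not overlap, which argues against it as the whole cause. The stellate median was -0.10 in gene bodies and -0.30 in introns, where the macrophage median was -0.39 and the endothelial median -0.05. Pericentral and periportal hepatocyte markers, which fewer hepatocytes would lower in female liver, lay toward female liver (median log2 ratios -0.42 and -0.28). Complement and serpin clade A genes lay toward male liver (0.26 and 0.59). With groups of liver genes going both ways, a part played by a lower share of hepatocytes stays open. A larger number of macrophages in female liver, or more of these transcripts per macrophage, may account for the pattern; neither was tested, and age range and pool size went with sex.

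Of the acute phase genes, 10 were higher in male gene bodies (median fold 1.96) with no intron call, and their median log2 ratio in introns was 0.07. Too few intronic reads would be a technical cause: their median intronic FPKM was 26.7 times that of called genes with an intron call, but the table gives no number of reads, and by intronic FPKM times the span of the gene 3 of 10 (Lcn2, Orm2 and Saa3) lay below the median of those genes, so it stays open. Their log2 ratios in introns ran from -1.14 to 0.79. Their adjusted p-values lay at the median percentile 65 (46 to 98) among called genes of like fold and expression. Those genes were not matched for gene length or number of reads, which also set the p-value. The median span of the 10 genes was 3.51 kb, against 26.6 kb in called genes with an intron call. So the percentile cannot tell a larger spread between pools, as a response in some pools could give, from fewer reads. A sex difference in RNA stability, or intronic RNA sampled at another time than the mature RNA of a short response, stays open and was not tested.

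In the list of clock and output genes 6 members were called higher in male liver (Ciart, Tsku, Dbp, Per2, Per3 and Tef). Their median fold was 2.08, but they were picked by their call, and the median log2 ratio of all 18 measured members was 0.13. Per1, Nr1d1, Hlf and Nr1d2 had log2 ratios of 0.03, 0.12, 0.14 and 0.26 with no call, and Npas2 was called higher in female liver. If the pools of the sexes were collected at different clock times, genes that peak at the opposite time could be lower in male liver, and Arntl, Npas2, Nfil3, Cry1 and Clock had a median log2 ratio of -0.22, with 4 of 5 below 0 and 1 of 5 called. A difference in collection time and a sex difference of the clock cannot be told apart, since the labels give no time of collection and each pool holds animals of 1 sex.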
